A study of Mus musculus with 6 samples.

How the data were processed

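The series holds 6 droplet single-cell RNA libraries of sorted mouse lung cells, which the labels place in 6 groups of 1 library. Per the submitters' processing notes, Cell Ranger, Seurat and Signac were used with the mouse genome build mm10, without stated versions; what each tool was used for is not given in the sources used here. Per the series' design text, each deposited file set was made from a control and its mutant together. Of each of the 3 aggregated matrices, the barcode list and the gene list were analysed here. The barcode list holds one cell barcode per line, of 16 bases and a suffix, and the gene list holds an Ensembl identifier, a symbol and a feature type. These files hold no measured values, and 0 count matrices were used here. The names of the deposited sets describe them as filtered, so a barcode is taken as a cell kept by the authors; the rule that kept it, any removal of doublets, the chemistry and any equalising of depth between libraries are not given in the sources used here. The depth behind each cell is therefore unknown. Because such filters set the number of barcodes, that number reflects loading, recovery and filtering, not the number of cells in the lung.

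Barcodes were counted per matrix and per suffix. A suffix was treated as a library because each matrix has 2 suffixes and 2 labelled libraries. No suffix was assigned to a genotype, since neither the files nor the labels tie one to a library and the order of libraries was not used as evidence. The comparisons of gene expression that had been planned in case of count matrices were not run, since counts per cell were not analysed here. For the same reason cell type shares were not compared. Sequences found under both suffixes were counted by exact match of all bases. Shares have 95% exact Clopper-Pearson intervals. The size of the pool from which barcodes would have been drawn at random is the product of 2 libraries' barcode numbers over the number they share, summed over pairs, with an exact Poisson interval of the shared number. The rates within and between matrices were compared with a two-sided exact binomial test, in which pairs were taken as independent although a library enters several pairs. On simulated libraries of the real sizes, drawn from pools of 2 known sizes, the estimate from pairs within matrices lay between 83.2 and 138.2% of the true size and 36 of its 40 intervals held it. The estimate from pairs between matrices lay between 93.3 and 114.8%, and 38 of its 40 intervals held the true size.

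The files give no coordinates. Gene positions, transcripts and neighbours were taken from GENCODE M21 on GRCm38, the assembly that mm10 names. The annotation release behind the gene list is not given in the sources used here. Of its 32285 identifiers, 32235 (99.8%) were found in GENCODE M21 and 50 were not; 733 of those found carry another symbol there. Matching was by identifier, and 38 symbols in the list belong to more than 1 identifier. Neighbours and overlaps were sought among listed genes found in GENCODE M21, and overlaps of Cebpa and Car4 among all its genes; distances are gaps between gene bodies. The principal transcript is the longest one that the annotation tags as principal. The genes named were Cebpa, Car4 and 63 markers of lung cell types (which include both), fixed before the data were examined; the neighbouring genes were named by their distance, the 3 nearest listed and the 3 nearest listed protein-coding genes on each side being computed, a rule added afterwards. Alternatives tried were counting distinct sequences only, leaving out sequences found under both suffixes, keeping only sequences found in no other matrix and taking pairs of libraries from different matrices. Python 3.11.15 with SciPy 1.17.1, NumPy 2.4.6 and matplotlib 3.10.9 was used.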

Results

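Single-cell RNA libraries were prepared from sorted mouse lung cells of the epithelial, immune, endothelial and mesenchymal compartments, on a droplet platform that gives each captured cell a barcode. The labels place the 6 libraries in 3 pairs of a control and a mutant, with 1 library per group, and the title of the study states its question: whether distal regulatory elements are needed for expression of Cebpa and Car4 in their own lung cell types. Cebpa encodes a CCAAT/enhancer-binding transcription factor expressed in alveolar type 2 (AT2) cells, the surfactant-producing epithelial cells. Car4 encodes carbonic anhydrase 4, a membrane-anchored enzyme that marks one of the lung's capillary endothelial cell types. The Car4 pair was taken at postnatal day 24, the first Cebpa pair at postnatal day 14 and the second Cebpa pair at postnatal day 35. By their labels, the day 24 control was heterozygous (het) and its mutant homozygous (hom). The day 14 control and mutant were het and hom in the same way. The label lines with these words, such as Car4-het and P14-Cebpa-hom, name the locus but not the altered allele. The day 35 pair set a wildtype library against a mutant described as het, which is the word given to the control at day 14, so mutant does not carry the same label at the 2 Cebpa ages. A separate genotype field reads WT for all 6 libraries and was not used for grouping. The labels pool male and female animals and give no number of animals.

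The values analysed here were the cell barcodes and the gene list of each pair's aggregated matrix. Counts per cell and gene were not analysed here, so no level of Cebpa, Car4 or any other gene, no cell type share and no UMI depth is given for any library, and no control was compared with its mutant.

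Cebpa and Car4 were both among the listed genes, each under a single identifier. Cebpa (ENSMUSG00000034957) lies on chromosome 7 from 35119293 to 35121928 on the plus strand of GRCm38, a span of 2636 bp. Its principal transcript has 1 exon of 2626 bp, of which 1077 bp are coding sequence and 1549 bp are untranslated, and it has no intron. Car4 (ENSMUSG00000000805) lies on chromosome 11 from 84957786 to 84966044 on the plus strand, a span of 8259 bp. Its principal transcript joins 8 exons into 1256 bp, of which 915 bp are coding sequence and 341 bp are untranslated.

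The nearest listed protein-coding genes to Cebpa were Cebpg, which encodes another CCAAT/enhancer-binding protein, 62.7 kb away on the side of lower coordinates, and Slc7a10, an amino acid transporter gene, 64.5 kb away on the other side. Pepd, the gene of the dipeptidase prolidase, followed at 74.6 kb and Lrp3 at 78.1 kb. Between Cebpa and these genes lie the long noncoding genes Gm35665, at 13.1 kb, Gm35611, at 28.4 kb, and Gm45096, at 52.6 kb. The antisense gene Gm45091 (chromosome 7, 35118044 to 35119605, minus strand) shares 313 bp with the 5′ end of Cebpa and is listed as a gene of its own. The nearest listed gene to Car4 was Usp32, a ubiquitin-specific protease gene, 18.4 kb away on the side of higher coordinates. On the other side of Car4 the nearest were Znhit3 at 41.4 kb, Myo19, a myosin gene, at 46.6 kb and Pigw at 77.5 kb. Beyond Usp32 the next listed genes, 1700125H20Rik and Appbp2, lie 204.4 and 221.2 kb from Car4. No annotated gene overlapped Car4 on either strand. Within 500 kb on either side, 24 listed genes other than Gm45091 surround Cebpa, 15 of them protein-coding, and 18 surround Car4, 13 of them protein-coding.

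**Figure D1:**
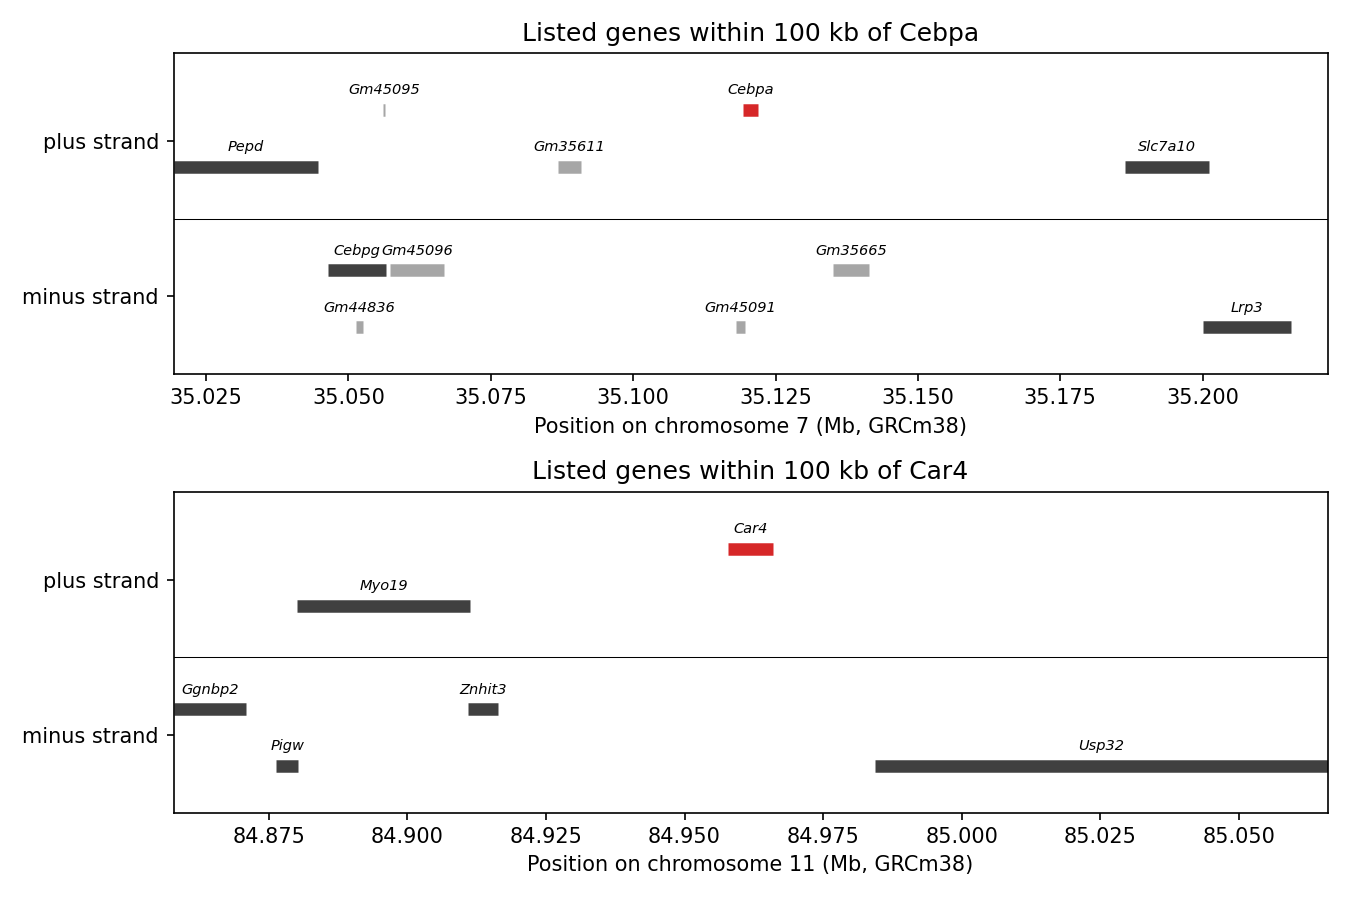
Listed genes within 100 kb of Cebpa (top, chromosome 7) and Car4 (bottom, chromosome 11), drawn to scale by GRCm38 position in Mb, with the plus strand above and the minus strand below the line; red is the named gene, dark grey other protein-coding genes and light grey noncoding genes, and height within a strand only separates names. Pepd, Ggnbp2 and Usp32 extend beyond the drawn range and are cut at its edge. Gm45091 overlaps the 5′ end of Cebpa on the minus strand. Car4 is overlapped by no gene, and the nearest edge of Usp32, its 3′ end, lies 18.4 kb away.

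The same gene list, of 32285 genes, was used for all 3 matrices, so a gene measured in one pair was measurable in the others. By annotation, 21702 of its genes were protein-coding, 697 were immunoglobulin or T-cell receptor genes and 9836 were noncoding or of another class. Every identifier was a mouse Ensembl gene, and no reporter or recombinase transgene had an entry of its own. All 63 marker genes fixed for the lung's cell types were listed under 1 identifier each. They comprised 10 AT2 genes such as Sftpc (surfactant protein C) and Lamp3, 8 alveolar type 1 genes such as Ager and Hopx, 6 genes of the Car4 capillary endothelium such as Ednrb (endothelin receptor type B) and Apln (apelin), and 4 of the other capillary type such as Plvap and Gpihbp1. There were also 3 each for ciliated, secretory, arterial, venous and lymphatic cells, 9 each for mesenchymal and immune cells and 2 for proliferation. None of the 63 overlapped another listed gene on its own strand. For 14 of them a listed gene lay on the opposite strand: among the AT2 genes these were Cebpa, Abca3 and Napsa, and among the alveolar type 1 genes Hopx, Rtkn2 and Cav1. None of the 6 Car4 endothelial genes had such a partner.

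The 3 matrices held 62624 cell barcodes in all. The Car4 matrix at day 24 held 22892, the Cebpa matrix at day 14 held 22133 and the Cebpa matrix at day 35 held 17599. Each barcode carries the suffix 1 or 2, as many suffixes as labelled libraries, but the sources used here do not say which suffix is the control and which the mutant, so the suffixes are not named by genotype. In the Car4 matrix suffix 1 had 13567 barcodes and suffix 2 had 9325, a ratio of 1.45, and suffix 1 made up 59.3% of the barcodes (95% exact Clopper-Pearson interval 58.6 to 59.9%). The Cebpa matrices were closer to even. At day 14 the suffixes had 11297 and 10836 barcodes, a ratio of 1.04, and at day 35 they had 8497 and 9102, a ratio of 1.07. The share of suffix 1 was 51.0% (50.4 to 51.7%) at day 14 and 48.3% (47.5 to 49.0%) at day 35. These intervals cover counting error only, and with 1 library per group the difference between libraries has no replicate check.

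**Figure D2:**
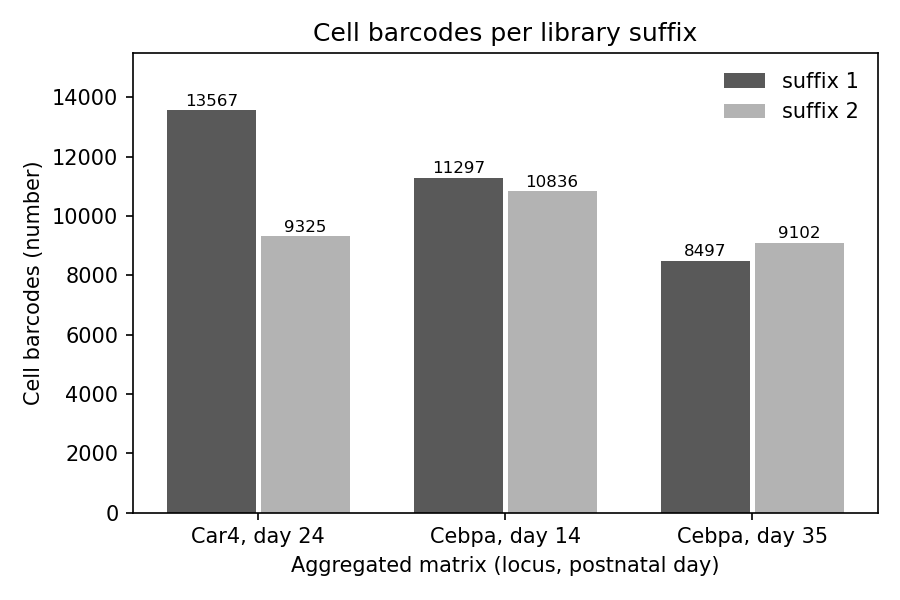
Number of cell barcodes (vertical axis) with suffix 1 (dark bars) and suffix 2 (light bars) in the aggregated matrices of the Car4 pair and the 2 Cebpa pairs (horizontal axis, with the postnatal day); each bar is 1 count, without replicates or error bars, and suffixes are not assigned to control or mutant. The Car4 matrix has 13567 against 9325 barcodes, whereas the Cebpa matrices differ by 461 and 605 barcodes.

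A few barcode sequences occurred under both suffixes of a matrix. There were 38 in the Car4 matrix, which is 0.166% of its 22854 distinct sequences (95% exact interval 0.118 to 0.228%). The Cebpa matrices had 31 of 22102 (0.140%, 0.095 to 0.199%) at day 14 and 21 of 17578 (0.119%, 0.074 to 0.183%) at day 35. As a background measured the same way, the 12 pairs of libraries from different matrices shared 21 to 52 sequences each, against 21 to 38 within a matrix. Per possible pair of barcodes, the rate within a matrix was 0.92 times that between matrices (95% interval 0.73 to 1.16, p = 0.53, two-sided exact binomial test on 90 shared sequences within and 388 between matrices), so no difference was detected. A random draw of barcodes would give such overlaps from a pool of about 3630000 sequences, estimated from the pairs within a matrix (95% interval 2950000 to 4510000).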

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

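The 13 values of barcode numbers, shares and pool size were each recomputed with 1 other choice, fixed before the data were examined. The choices for the counts remove only the 38, 31 and 21 sequences found under both suffixes, so they could hardly move a count and say nothing about its stability. Counting distinct sequences only gave 22854 barcodes for the Car4 matrix, 22102 for the Cebpa matrix at day 14 and 17578 at day 35. Keeping only sequences found in no other matrix gave shares under both suffixes of 0.159%, 0.142% and 0.121% in the same order. That choice kept 36 of the 38, all 31 and all 21 shared sequences, so it too could hardly move a share. Pairs of libraries from different matrices gave a pool of about 3350000 sequences (95% interval 3030000 to 3710000) in place of 3630000, inside the interval of the latter (2950000 to 4510000). The other choices foreseen for expression of Cebpa and Car4 and for named genes were not run, since counts per cell were not analysed here. Cell type shares were not computed either. With 1 library per group no replicate could be left out, and no split of samples into other groups applies.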

Other observations

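The test in this part was chosen after the shared sequences had been counted. One explanation for barcode sequences found under both suffixes of a matrix is that cells or reads of one library were counted again in the other. If confined to libraries of the same matrix, that would raise sharing within a matrix over sharing between matrices. The ratio was 0.92 (95% interval 0.73 to 1.16), which argues against an excess within a matrix larger than the upper bound. A smaller one stays open. Recounting that also crossed matrices would raise both rates, so this ratio cannot test it. At the rate between matrices, 97.4 shared sequences would be found within matrices, against 90 counted. Random reuse of barcodes from one pool could give such numbers, but so could recounting across all matrices. No biological explanation was tested.

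If counts per cell are examined, 2 points of the labels and the annotation bear on how they are read. The word het names the control at day 14 and the mutant at day 35 of the Cebpa pairs. The antisense gene Gm45091 shares 313 bp with Cebpa by gene span, and exons of the 2 genes were not compared. If reads of both genes fall in that stretch, they are separable only where counting uses strand.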
